A study of Mus musculus with 5 samples.

How the data were processed

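The series profiled microRNAs (miRNAs, small RNAs that repress messenger RNAs) in C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is lowered. There were 5 groups: proliferating cells taken at 70 to 80% confluence, cells at 100% confluence, and cells taken 1, 2 or 4 days after induction in 2% horse serum. Per the labels, total RNA was extracted with Trizol, each group had 4 biological replicates, and each replicate was hybridised on a 2-colour array against a common reference, a pool of the 4 proliferating replicates. In every group 2 replicates carried Cy3 and 2 carried Cy5, per the labels' series design. Each group came as 4 scanner files, so 20 arrays were used, and each array was taken as 1 replicate. The replicate numbers used below follow the order of these files and link no arrays between groups.

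The deposited scanner files hold spot intensities on a linear scale, per the file headers: a mean and a median foreground and a local background for the red and the green channel. They carry no quality flag, no spread of the background, no slide or scan date and no record of which dye the cells' RNA carried. Each array has 3072 spots. 1487 probes are printed in 2 spots each, and 98 spots are empty. Of the probes, 1436 are for miRNAs, and 343 of these are named for mouse. 265 are named for human or rat but not mouse, 685 for other organisms only, and 143 are unnamed proprietary sequences (miR-Plus). A further 12 probes are for small nuclear or nucleolar RNAs, 8 are negative controls, 10 are spikes and 21 have no known status. The authors also deposited a table with 1 value per probe and group. Set against the scanner files, its columns for confluent cells and days 1, 2 and 4 were log2 ratios of that group over proliferating cells, with an R² of 0.799 to 0.909 on the 20 arrays. Its proliferating column was unrelated to any array (R² 0.0106) and was not used. The medians of the authors' deposited log2 columns were 0 for proliferating, 0 for confluent, 0.00432 for day 1, -0.016 for day 2 and -0.0058 for day 4. The scanner settings and the authors' normalization are not given in the sources used here.

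The dye orientation of each array was recovered from the authors' table. Each of its columns was regressed on the red over green log2 ratios of all 20 arrays, and the sign of an array's weight in the column of its own group gave its orientation. The arrays of proliferating cells had no such column, so their orientation was read from their weights in the other 4 columns, which carried the opposite sign. This step for the proliferating arrays was not part of the plan fixed beforehand, and every comparison with proliferating cells rests on it. Deciding weights lay between 0.112 and 0.255 in size, against at most 0.0249 for unrelated arrays. The outcome, 2 arrays of each orientation in every group, matched the labelled design. Arrays of one orientation correlated at 0.0734 to 0.78 over all probes. The direction of every difference below rests on the sign of the authors' table and is called likely: the labels put the cells' RNA in the second channel, and the table's sign gives a rise of the muscle miRNAs after induction, as is textbook knowledge of this cell line. A reversed sign would exchange higher and lower throughout and leave the counts of called probes as they are. Counts of arrays above background within a group use the channel taken to hold the cells' RNA. These counts, and bounds based on them, could change.

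Intensities were corrected with limma's normexp method (offset 50) and normalized by global loess within each array, with control spots at weight 0, and the 2 spots of a probe were averaged. A probe was detected on an array when its background-subtracted mean exceeded the 95th percentile of the empty and negative control spots in either channel. Counts out of the 4 arrays of a group use only the channel taken to hold the cells' RNA. The 593 miRNA probes detected on at least 4 of the 20 arrays were tested, 196 of them named for mouse. All species were kept, because related sequences can bind a mouse miRNA. Differences between groups were tested with limma's moderated test (lmFit and eBayes, two-sided) on log2 ratios, with 1 coefficient per group entered with the sign of the orientation and 1 dye coefficient, and with the Benjamini-Hochberg adjustment at 0.05 within each comparison. All 20 arrays shared one estimate of the spread per probe, with 14 residual degrees of freedom. The reference pool cancels in each difference. The dye coefficient passed the threshold for 369 of the 593 probes, with a median size of 0.187 on the log2 scale. A moderated F test over the 4 differences from proliferating cells asked for any change over time. Values given per group are log2 ratios to the reference pool with the dye coefficient removed, as mean ± SD over 4 arrays.

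The 20 miRNA lists, the tests, the alternatives and the rule for named probes were fixed before the data were examined. Lists of at least 2 tested members were tested with fry, whose directional p asks whether members move one way on balance and whose mixed p asks whether they change in either direction. Neither sets a list against other probes. Members are counted per probe, in the counts and in the tests, so miR-20a, with 2 probes, counts as 2 members. Camera, with a preset correlation of 0.01 and with an estimated correlation, was the alternative. The lists are muscle miRNAs, myoblast differentiation literature, the miR-17-92 and paralogue clusters, the let-7, miR-26, miR-29, miR-30, miR-181, miR-15/16 and miR-34 families, the miR-23/24/27, miR-199 and miR-214, miR-221 and miR-222, and Dlk1-Dio3 clusters, and miRNAs of embryonic stem cells, neurons, blood cells, epithelia, liver and of smooth muscle, fibroblasts and endothelium. For each comparison with proliferating cells the text names the 10 highest and 10 lowest log2 differences among called probes whose 4 arrays all lie on the same side of the proliferating mean, for each step between time points 5 and 5 by the same rule, every tested member of the muscle and myoblast lists, and up to 4 members of any other list described. Probe names are those of the array and can be old: miR-422b was later renamed miR-378, and the array has a separate probe named miR-378. The myoblast list matched the latter by name. Which of these probes measures the miR-378 of the literature could not be checked without probe sequences. A RefSeq table of assembly GRCm38.p6 was used only to see which miRNA genes neighbour each other within 50 kb, and no probe was renamed through it.

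A called probe that was above background on no array of a group has only a bound there. It was computed per channel after loess and Aquantile normalization as the brighter group's mean over the dimmer group's, with each dim array set to the higher of its own value and the lowest signal among its detected probes. Alternatives covered the background correction, the normalization within and between arrays, the detection filter, the probes and foreground used, the dye term, the groups in the fit, the pool as control, the spread, array weights and leaving out each array. Counts of settings in which a call held include the authors' deposited value, which has no test and counted as held within 1 SD between arrays. They also include Aquantile normalization between arrays, which leaves the ratios unchanged and cannot end a call. Such counts are thus higher than tests alone would give. The fit was tested on simulated data: with 200 of 593 probes changed in day 4 against proliferating and 20 draws, 58.5% of changes of 0.5 on the log2 scale, 97.1% of changes of 1 and 100% of changes of 2 and of 4 were called, and 2.76% of the calls were false. At most 36 probes were called in a real comparison. The Benjamini-Hochberg adjustment is stricter where fewer probes change, so the simulated shares likely overstate what the real comparisons could find. A probe not called is therefore not shown to be unchanged. R 4.3.3 and limma 3.58.1 were used. The number of arrays limits the precision: the median standard error of a difference was 0.18 on the log2 scale.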

Results

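The arrays followed miRNAs of C2C12 myoblasts from proliferation through confluence to 4 days of differentiation, with 5 groups of 4 biological replicates. Between 346 and 630 of the 1436 miRNA probes were detected per array. The detection limits, in units of scanner intensity above local background, lay between 160 and 843 in red and between 88.4 and 456 in green. No pair of arrays of a group held identical values. Day 1 replicate 2 stood apart from the other arrays of its group, with an SD between duplicate spots of 0.458 on the log2 scale against 0.163 to 0.206 on the other day 1 arrays.

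A first count did not rest on the dye orientation. The log2 ratio to the proliferating pool, whatever its sign, was beyond 1 on all 4 arrays for 0 probes in proliferating and in confluent cells, for 3 probes at day 1, 6 at day 2 and 11 at day 4. For miR-206, a miRNA made in skeletal muscle, its size lay between 2.95 and 3.17 at day 1, between 3.24 and 4.32 at day 2 and between 3.83 and 4.49 at day 4. The dye effect was not removed from this count or these sizes. Of the counted probes, rno-miR-1 at day 2 and ptc-miR-480a at day 4 were not among limma's calls below. All directions that follow are likely directions, taken from the sign of the authors' deposited table.

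Of 5 tested miRNAs with known roles in skeletal muscle, 2 were higher than in proliferating cells at day 1 and 3 at days 2 and 4. Of 11 tested probes of the miR-17-92 and paralogue clusters, which are linked to proliferation, 0 were lower at day 1, 3 at day 2 and 5 at day 4. The 5 include 2 probes of miR-20a, and hsa-miR-18b beside miR-18. Days 2 and 4 were not set against confluent cells, so density and induction are not told apart in these falls. Over the whole time course 43 of the 593 tested probes changed by limma's moderated F test at an adjusted p under 0.05, and 42 did so without day 1 replicate 2. Against proliferating cells, limma called 0 probes at confluence, 9 at day 1, 23 at day 2 and 36 at day 4. Of the 16 probes higher at day 2, 13 were also higher at day 4, and all 7 lower at day 2 were lower at day 4. Lists drawn independently would share 0.54 and 0.189. Both comparisons use the same proliferating arrays. Unchanged groups simulated against them shared on average 0 calls, but unchanged groups leave almost no calls to share. That 0 thus cannot show how much the shared arrays add to the real overlap. The differences at days 2 and 4 correlated at 0.912 across probes, which are not independent replicates, against 0.497 in the simulation and 0.673 with the proliferating arrays divided between the comparisons. Their covariance was 0.155 against 0.0194 simulated.

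**Figure D1:**
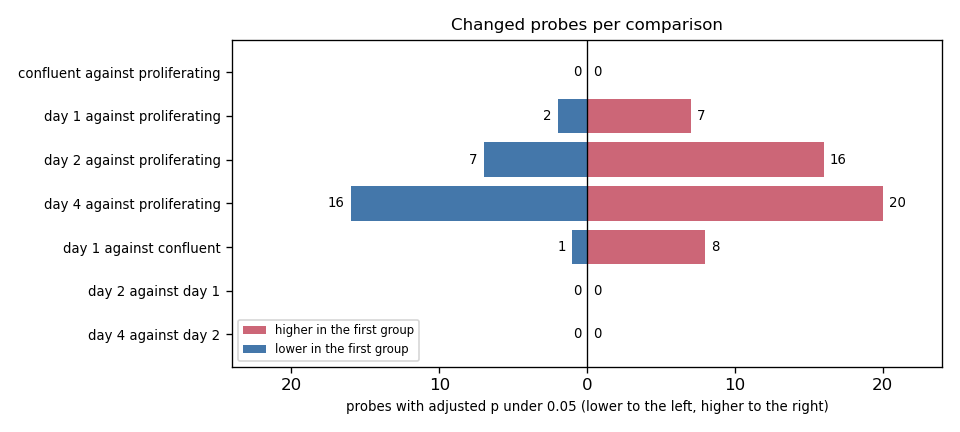
Bars give the number of probes past the threshold in each comparison, out of 593 tested, with probes higher in the first group to the right and lower to the left. Calls against proliferating cells number 9 at day 1, 23 at day 2 and 36 at day 4, and 0 at confluence and in the steps from day 1 to day 2 and from day 2 to day 4.

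Cells at full confluence were compared with proliferating cells to ask what density alone changes before serum is withdrawn. No probe passed limma's test. 33 probes had an unadjusted p under 0.05, where chance gives 29.6. The lowest adjusted p, 0.364, was that of miR-709, at 0.65 ± 0.16 (SE) on the log2 scale and higher on 4 of 4 arrays; it was chosen after its values were seen. Without background correction and with plain background subtraction 1 probe was called, higher at confluence. Among the muscle miRNAs, miR-206 differed by 0.34 ± 0.28 (SE), the shared miR-133a and miR-133b probe by 0.34 ± 0.25, miR-1 by -0.04 ± 0.41, miR-486 by 0.01 ± 0.16 and miR-499 by -0.24 ± 0.30 on the log2 scale. In the myoblast differentiation list, 15 members were tested and 0 passed, also when adjusted over the list alone. miR-26a differed by -0.37 ± 0.16 and lay lower on 4 of 4 arrays, with an adjusted p of 0.838. The members miR-29a, miR-378, miR-29c, miR-181b, miR-155, miR-24, miR-27b and miR-29b lay between -0.45 and -0.01. miR-221, miR-424, miR-214, miR-222, miR-503 and miR-125b lay between 0.01 and 0.19. No list passed the fry test at confluence, and the lowest adjusted p was 0.312 for the miR-26 family. In the miR-17-92 and paralogue clusters 0 of 11 members passed. There 9 differences were negative and 2 positive, with a mean of -0.15 (fry adjusted p = 0.674).

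After 1 day in low serum, which asks for the first response to induction, the probes for miR-206 and miR-133 led the changes. miR-206 rose 8.29-fold over proliferating cells (log2 3.05 ± 0.28, SE, adjusted p = 3.07e-07), from a mean log2 ratio to the pool of 0.04 ± 0.42 to 3.09 ± 0.16 (SD, n = 4). The shared miR-133a and miR-133b probe, for miRNAs of heart and skeletal muscle, rose 4.99-fold (log2 2.32 ± 0.25, adjusted p = 2.72e-06). The macaque probe mml-miR-133a rose with it by 2.44 ± 0.29. miR-1, which shares gene clusters with miR-133a, differed by 0.07 ± 0.41 and was above background on 1 of 4 arrays of proliferating cells. Of the other muscle miRNAs, miR-499 differed by -0.67 ± 0.30 and miR-486 by 0.05 ± 0.16, and neither passed. The muscle list thus had 2 of 5 tested members higher, as when adjusted over the list alone, and rose by fry (adjusted p = 0.00224; adjusted p = 0.387 by camera with an estimated correlation). The list of smooth muscle, fibroblast and endothelial miRNAs had 3 members tested and 0 called, against 1 higher adjusted over the list alone. It passed fry with a mean of 0.33 (adjusted p = 0.0438, and adjusted p = 0.387 by camera with an estimated correlation).

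The remaining 6 called probes at day 1 were not named for mouse. The unnamed miR-Plus probes 17881, 17864 and 17950 rose by 1.14, 0.77 and 0.62 and the herpesvirus probe rlcv-miR-rL12 by 0.94. These probes already lay above the pool on all 4 confluent arrays. Log2 ratios there were 0.14 to 0.47 for probe 17881 and 0.05 to 0.61 for probe 17864. They were 0.08 to 0.59 for probe 17950 and 0.19 to 0.55 for rlcv-miR-rL12. Only probe 17881 of these was also called against confluent cells, so a rise from induction is not shown for the others. The insect probe aga-miR-7 fell by 1.19 and hsa-miR-617 fell by 0.59 on the log2 scale. The split was 7 higher and 2 lower, against 8 and 0 with median centring and 6 and 3 with scale normalization. In the miR-17-92 and paralogue clusters 0 of 11 members passed at day 1, against 2 lower when adjusted over the list alone, and all 11 differences were negative (fry adjusted p = 0.0846). In the myoblast list 0 of 15 members passed, also adjusted over the list alone: miR-27b, miR-24, miR-26a, miR-214, miR-424, miR-503, miR-181b and miR-378 lay between 0.01 and 0.49, and miR-29b, miR-29a, miR-29c, miR-125b, miR-222, miR-155 and miR-221 between -0.36 and -0.07. Without day 1 replicate 2, with its noisier spots, 5 probes were called; of the 4 that lost the call, aga-miR-7 and probe 17950 did not shrink, at -1.20 and 0.66, while probe 17864 and rlcv-miR-rL12 lay at 0.65 and 0.71. In other settings aga-miR-7 kept its call in 11 of 23, probe 17950 in 11 of 24, and probe 17864 and rlcv-miR-rL12 each in 16 of 24. Without proliferating replicate 4 the count was 4 and without proliferating replicate 3 it was 17, while miR-206, the shared miR-133a and miR-133b probe, mml-miR-133a and probe 17881 were called with each array left out.

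Day 1 was also set against confluent cells. miR-206 was 6.53-fold higher (log2 2.71 ± 0.28, adjusted p = 2.38e-06) and the shared miR-133a and miR-133b probe 3.95-fold higher (log2 1.98 ± 0.25, adjusted p = 3.35e-05), with mml-miR-133a higher by 2.12 ± 0.29. miR-422b rose by 1.13 ± 0.24 (adjusted p = 0.0112) and miR-143, a miRNA abundant in smooth muscle and fibroblasts, by 0.94 ± 0.17 (adjusted p = 0.00292). In total 9 probes were called, 8 higher and 1 lower. The others were miR-26a at 0.83, miR-23b at 0.59, probe 17881 at 0.72 and hsa-miR-617, the lower one, at -0.49; miR-26a, miR-23b and probe 17881 fall outside the naming rule and were chosen after their values were seen. All of the called probes had their 4 day 1 arrays on one side of the confluent mean. Median centring, loess on detected spots and scale normalization gave 5, 6 and 5 higher and 0 lower. The count was 5 without confluent replicate 1 and also 5 without day 1 replicate 4, and each of these ended the call of miR-422b, whose difference lay between 0.89 and 1.22 in the 24 other settings. The call of hsa-miR-617 held in 9 of 23 other settings.

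At day 2, 16 probes were higher than in proliferating cells and 7 were lower. miR-206 was 12.9-fold above proliferating cells (log2 3.69 ± 0.28, adjusted p = 5.10e-09) and the shared miR-133a and miR-133b probe 10.3-fold (log2 3.36 ± 0.25, adjusted p = 5.10e-09). miR-1 rose 2.81-fold (log2 1.49 ± 0.41, adjusted p = 0.0464), on 4 of 4 arrays above the proliferating mean. Its replicates spread widely, at 1.83 ± 0.99 (SD, n = 4), 1 of 4 proliferating arrays measured it above background, and its call held in 9 of 25 other settings. Probes of other organisms for the same miRNAs rose too: mml-miR-133a by 3.31, dre-miR-133c by 1.48 and aga-miR-1 by 1.29, the last 2 above background on 2 of 4 proliferating arrays each and with calls held in 13 and 15 of 24 other settings. miR-133a*, the opposite strand of miR-133a, was not well above background on any proliferating array and was detected on 2 of 4 day 2 arrays, at least 1.36-fold higher (adjusted p = 0.0217). That call held in 15 of 25 other settings, and with loess fitted on detected spots the log2 difference was 0.16, below that bound. miR-422b rose by 1.26 ± 0.24, miR-143 by 0.88 ± 0.17 and miR-27b by 0.87 ± 0.20. miR-486 and miR-499 differed by 0.06 ± 0.16 and 0.30 ± 0.30 and did not pass. The muscle list had 3 of 5 members higher, also when adjusted over the list alone (fry adjusted p = 4.84e-06; adjusted p = 0.0106 by camera with an estimated correlation).

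Among the 7 probes lower at day 2 were 3 of the 11 tested members of the miR-17-92 and paralogue clusters, and 6 members were lower when adjusted over the list alone. miR-20a (probe 11008) fell by 1.12 ± 0.21, miR-17-5p by 1.04 ± 0.19 and miR-18 by 0.86 ± 0.20 on the log2 scale, with adjusted p of 0.00316, 0.00252 and 0.0184. The list moved down by fry (adjusted p = 0.00981; adjusted p = 0.132 by camera with an estimated correlation). miR-222, known to target the cell cycle inhibitor p27, fell by 0.87 ± 0.21, the insect probe aga-miR-7 by 1.76, probe 17810 by 0.66 and miR-15b by 0.57. aga-miR-7 was above background on 1 of 4 day 2 arrays, so the size of its fall is uncertain. In other settings the call of miR-222 held in 18 of 26, that of miR-15b in 14 of 26 and that of probe 17810 in 14 of 24. The myoblast differentiation list moved in both directions, with a mixed fry adjusted p of 1.16e-06 and a directional adjusted p of 0.744. miR-26a, which is reported to target the histone methyltransferase Ezh2, rose by 0.63 ± 0.16, with its call held in 16 of 26 other settings, together with miR-27b, and miR-222 fell, while the other 12 tested members did not pass over all probes; adjusted over the list alone, 3 were higher and 2 lower. Of those 12, miR-24, miR-181b, miR-503, miR-424, miR-378, miR-29b and miR-214 lay between 0.01 and 0.63, and miR-29a, miR-29c, miR-221, miR-155 and miR-125b between -0.58 and -0.24. The probe miR-422b, whose name was later changed to miR-378, is outside this list and rose by 1.26.

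Further lists passed fry at day 2. The pair of miR-221 and miR-222 moved down, with miR-222 as the 1 called member, also adjusted over the list alone (adjusted p = 0.00981; adjusted p = 0.132 by camera with an estimated correlation). The miR-26 family moved up, with miR-26a as 1 of 2, also adjusted over the list alone (adjusted p = 0.013; adjusted p = 0.161 by camera with an estimated correlation). The miR-23/24/27 clusters moved up, with miR-27b as 1 of 5 and 3 adjusted over the list alone (adjusted p = 0.0243; adjusted p = 0.191 by camera with an estimated correlation). The smooth muscle, fibroblast and endothelial list moved up, with miR-143 as 1 of 3, also adjusted over the list alone (adjusted p = 0.013; adjusted p = 0.209 by camera with an estimated correlation).

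The day 2 count of 23, 16 higher and 7 lower, became 10 higher and 11 lower with loess fitted on detected spots. It was 27 without day 1 replicate 2, but 14, 14, 15 and 9 without proliferating replicate 1, 3 or 4 or day 2 replicate 1. With each array left out, 8 of the 18 named probes stayed called: miR-206, the shared miR-133a and miR-133b probe, mml-miR-133a, miR-422b, miR-143, miR-17-5p, miR-20a (probe 11008) and aga-miR-7. The step from day 1 to day 2 gave 0 calls by limma, with 51 probes at an unadjusted p under 0.05 where chance gives 29.6. In that step the shared miR-133a and miR-133b probe differed by 1.04 ± 0.25 with an adjusted p of 0.141, the lowest adjusted p of the step; it was chosen after its value was seen.

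Day 4 showed the widest response among the 4 comparisons with proliferating cells. miR-206 stood 17.5-fold above proliferating cells (95% interval 11.7 to 26; log2 4.13 ± 0.28, adjusted p = 8.49e-10), at 4.17 ± 0.45 against 0.04 ± 0.42 (SD, n = 4). The shared miR-133a and miR-133b probe stood 12.7-fold above (8.88 to 18.2; adjusted p = 8.49e-10), miR-1 3.63-fold (2.00 to 6.61; adjusted p = 0.00652) and miR-422b 3.42-fold (2.42 to 4.82; adjusted p = 3.85e-05). miR-143 rose 2.26-fold (1.77 to 2.89) and miR-26a 2.20-fold (1.73 to 2.79), both with an adjusted p of 7.17e-05. mml-miR-133a, dre-miR-133c and aga-miR-1 rose by 3.49, 1.70 and 1.40 on the log2 scale and the herpesvirus probe mghv-miR--14 by 0.85. Genes of these miRNAs lie side by side in the mouse annotation, Mir206 next to Mir133b and Mir1a-1 next to Mir133a-2. The muscle list had 3 of 5 tested members higher, as when adjusted over the list alone (fry adjusted p = 7.65e-07; adjusted p = 0.00882 by camera with an estimated correlation). Its other members, miR-499 at 0.49 ± 0.30 and miR-486 at 0.14 ± 0.16, did not pass. The call of miR-1 ended with loess fitted on detected spots and with scale normalization. miR-208 was detected on too few arrays to be tested.

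**Figure D2:**
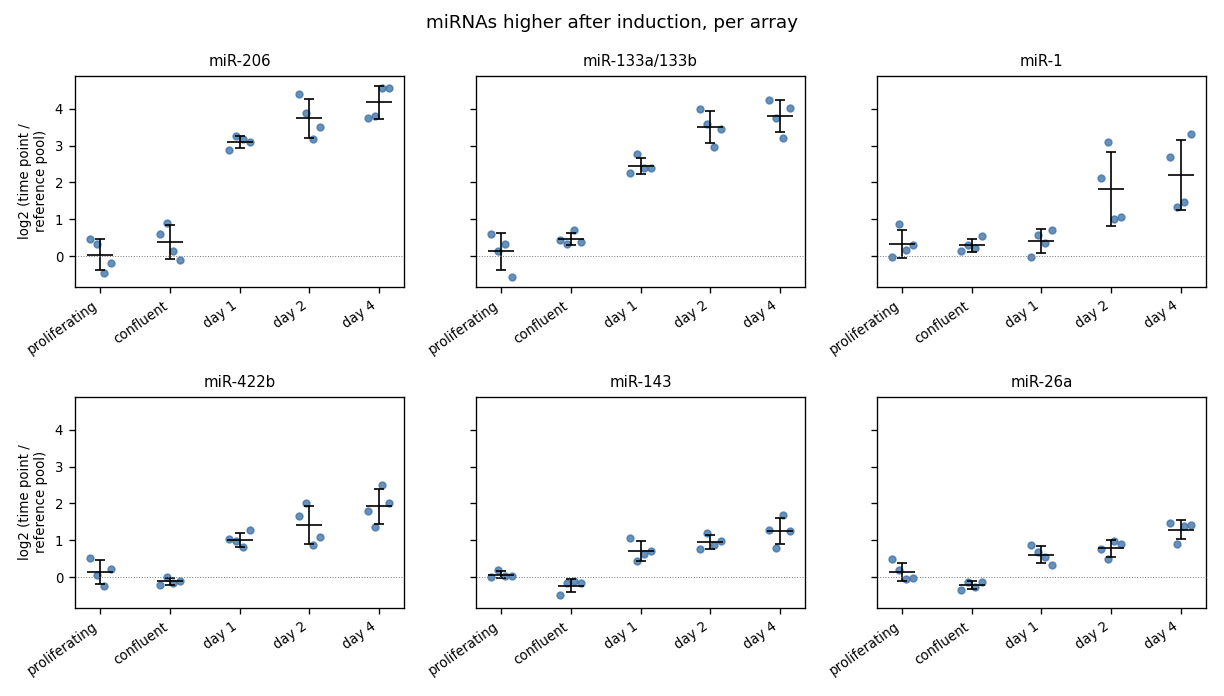
Each panel plots the log2 ratio of the time point to the proliferating reference pool, with the dye effect removed, on the vertical axis for the 5 groups on the horizontal axis. Points are the 4 arrays of a group, and bars give the mean and SD. miR-206 goes from 0.04 in proliferating cells to 4.17 at day 4, and miR-1 from 0.34 to 2.20 with a wider spread.

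Members of the miR-17-92 and paralogue clusters made up 5 of the 16 probes lower at day 4, out of 11 tested, and 5 when adjusted over the list alone. miR-20a (probe 11008) fell by 1.45 ± 0.21, miR-17-5p by 1.41 ± 0.19, miR-18 by 1.38 ± 0.20 and hsa-miR-18b by 1.15 ± 0.24 on the log2 scale, with adjusted p from 3.85e-05 to 0.00287. A second miR-20a probe (10999) fell by 0.95 ± 0.23. Because miR-20a is counted in both of its probes, the 5 probes are not 5 separate miRNAs. Whether hsa-miR-18b took up miR-18 was not tested. All 11 members had a negative difference, and the list moved down by fry (adjusted p = 0.000393; adjusted p = 0.0461 by camera with an estimated correlation). miR-19a and miR-19b, whose genes lie in the same cluster as those of miR-17, miR-18 and miR-20a, differed by -0.24 ± 0.28 and -0.12 ± 0.19 (SE); they were detected on only 9 and 8 of the 20 arrays.

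**Figure D3:**
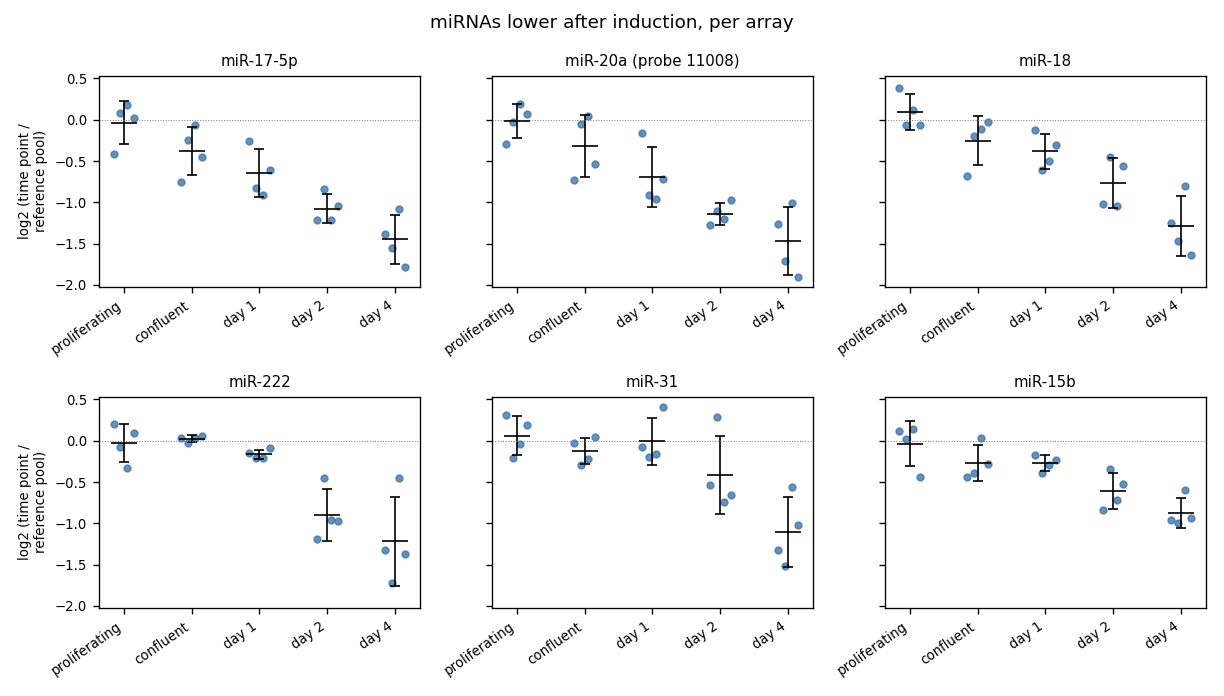
Each panel plots the log2 ratio of the time point to the proliferating reference pool, with the dye effect removed, on the vertical axis for the 5 groups on the horizontal axis. Points are the 4 arrays of a group, and bars give the mean and SD. miR-17-5p goes from -0.03 in proliferating cells to -1.45 at day 4, and miR-222 from -0.03 to -1.22.

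Further called probes fell at day 4. miR-222 fell 2.28-fold (1.69 to 3.07; adjusted p = 0.000589) and miR-31 2.24-fold (1.62 to 3.11; adjusted p = 0.00174). miR-182 fell by 0.90 ± 0.15 on the log2 scale, probe 17810 by 0.85 and aga-miR-7, above background on 2 of 4 day 4 arrays, by 1.58. miR-15b fell by 0.84 ± 0.16 as the called member of the miR-15/16 family, where 1 of 6 passed, also adjusted over the list alone, while miR-16, whose gene Mir16-2 neighbours Mir15b, differed by -0.68 ± 0.28 with an adjusted p of 0.204. That family moved down by fry (adjusted p = 0.0158; adjusted p = 0.21 by camera with an estimated correlation). In the pair of miR-221 and miR-222, miR-221 differed by -0.62 ± 0.21 and passed only when adjusted over the list alone, which called both members (fry adjusted p = 0.000414; adjusted p = 0.0513 by camera with an estimated correlation).

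In the myoblast differentiation list at day 4, miR-26a rose, miR-222 and miR-155 fell and the other 12 members did not pass. miR-155 fell by 0.67 ± 0.20 (adjusted p = 0.0449) and was above background on 1 of 4 day 4 arrays against 4 of 4 proliferating arrays, and its call held in 12 of 25 other settings. Adjusted over the list alone, 3 members were higher and 4 lower. The higher ones were miR-26a, miR-27b and miR-24, and the lower ones miR-222, miR-155, miR-125b and miR-221. miR-29a did not pass there either. miR-27b at 0.63 ± 0.20, miR-24 at 0.61 ± 0.18, miR-125b at -0.68 ± 0.21 and miR-29a at -0.54 ± 0.30 had adjusted p of 0.061, 0.0528, 0.061 and 0.445 over all probes. miR-378, miR-181b and miR-424 lay between 0.05 and 0.38, and miR-29c, miR-29b, miR-214 and miR-503 between -0.15 and -0.01. The probe named miR-422b, a name later changed to miR-378, is outside this list and rose 3.42-fold. Which probe measures the miR-378 of the literature was not checked, so the counts and tests of the list rest on probe names. The mixed fry adjusted p of the list was 3.68e-09 and its directional adjusted p 0.853.

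Other lists held few called members at day 4. miR-23b, with 1 of 5 members of the miR-23/24/27 clusters higher and 3 adjusted over the list alone, rose by 0.64 ± 0.14, and all 5 had positive differences (fry adjusted p = 0.00933; adjusted p = 0.174 by camera with an estimated correlation). Mir23b, Mir27b and Mir24-1 neighbour each other. In the miR-26 family 1 of 2 rose, also adjusted over the list alone (fry adjusted p = 0.000414; adjusted p = 0.0539 by camera with an estimated correlation), with miR-26b at 0.27 ± 0.21. miR-143 was the 1 of 3 tested smooth muscle, fibroblast and endothelial miRNAs that rose, also adjusted over the list alone, while miR-145, whose gene Mir145a neighbours Mir143, differed by -0.16 ± 0.16 (fry adjusted p = 0.0018; adjusted p = 0.174 by camera with an estimated correlation). miR-30b rose by 0.65 ± 0.15 as 1 of 5 in the miR-30 family, miR-382 fell by 0.50 ± 0.12 as 1 of 14 in the Dlk1-Dio3 cluster, and miR-150 rose by 0.74 ± 0.16 as the 1 tested blood cell miRNA, each also adjusted over the list alone; the first 2 lists had a fry adjusted p of 0.0607 each. miR-150 was above background on 1 of 4 proliferating arrays, and its call ended with median centring and with loess fitted on detected spots. The calls of miR-23b, miR-30b and miR-382 ended without the dye term, those of miR-23b and miR-382 also with median centring and those of miR-30b and miR-382 also with only the 2 groups compared; they held in 24, 24 and 21 of 26 other settings.

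No member was called at day 4, also adjusted over the list alone, in the let-7 family (8 tested, fry adjusted p = 0.726), the miR-29 family (3, 0.473), the miR-34 family (3, 0.919), the miR-181 family (2, 0.562), the cluster of miR-199 and miR-214 (4, 0.919), the neuronal list (4, 0.562) or the epithelial list (2, 0.942). A list's median differed in sign from its mean at confluence for the Dlk1-Dio3 list, the miR-15/16 list and the list of miR-199 and miR-214 and at day 1 for miR-15/16. The epithelial list at day 4 had a negative mean and an upward test. None of these passed. The embryonic stem cell list had 1 tested member, not called, and none of the liver list was tested. A probe named let-7a-e, outside these lists, rose by 0.55 ± 0.14 and was chosen after its value was seen.

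At day 4 all 36 called probes had their 4 arrays on one side of the proliferating mean, 25 were named for mouse and 11 were not. The split of 20 higher and 16 lower became 12 and 15 with loess fitted on detected spots, and 37 probes were called without day 1 replicate 2. With each array left out 22 of the 26 named probes stayed called; dre-miR-133c lost its call without proliferating replicate 4, miR-382 without day 4 replicate 2, miR-20a (probe 10999) without day 4 replicate 1 or 4, and miR-155 without any of proliferating replicates 1, 2 and 4 and day 4 replicates 1, 2 and 4. The step from day 2 to day 4 gave 0 calls by limma, with 23 probes at an unadjusted p under 0.05 where chance gives 29.6, and a smallest adjusted p of 0.967. In that step miR-26a differed by 0.51 ± 0.16 and miR-31 by -0.69 ± 0.23, both chosen after their values were seen.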

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

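All tests of other splits and of the patterns weighed here were planned, except the test on SNORD13 and the test on the sizes of the day 1 differences without day 1 replicate 2, which were chosen only after the result was seen.

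At single arrays, some named probes stood far from the other 3 of their group, on the log2 ratio to the pool. miR-26a lay at 0.90 on day 4 replicate 2 against 1.40 to 1.46 on the others. miR-15b lay at -0.60 on day 4 replicate 3 against -0.99 to -0.93. mghv-miR--14 lay at 1.20 on day 4 replicate 2 against 0.66 to 0.68. miR-143 lay at 0.21 on proliferating replicate 2 against 0.02 to 0.04, and at -0.48 on confluent replicate 1 against -0.16 to -0.11. miR-182 lay at 0.55 on proliferating replicate 1 against -0.07 to 0.01. miR-133a* lay at 0.23 on day 1 replicate 3 against 0.53 to 0.57. rlcv-miR-rL12 lay at 0.19 on confluent replicate 3 against 0.49 to 0.55, and probe 17950 at 0.87 on day 1 replicate 1 against 0.53 to 0.56. The SD between duplicate spots was 0.458 on day 1 replicate 2 against 0.163 to 0.206. Of 155 groups of 4 values tested, 10 held such an array, where chance at 1 in 20 gives 7.75.

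The effects at day 1 and at confluence, both against proliferating cells, differed for 9 probes by limma's test of the difference itself. The proliferating arrays cancel in that difference, so this restates the comparison of day 1 with confluent cells. The probes are miR-206 (2.71), mml-miR-133a (2.12), the shared miR-133a and miR-133b probe (1.98), miR-422b (1.13), miR-143 (0.94), miR-26a (0.83), probe 17881 (0.72), miR-23b (0.59) and hsa-miR-617 (-0.49), on the log2 scale.

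Of 8 detected small nuclear and nucleolar RNA probes, which the comparisons of miRNAs do not use, 3 changed at day 4 and 5 did not pass. The spliceosomal RNA U6, often used to scale miRNA measurements, fell in both of its probes on all 4 arrays of each day after induction. U6snRNA1 differed from proliferating cells by -0.51 at day 1, -1.03 at day 2 and -1.0 at day 4, and U6snRNA2 by -0.63, -1.02 and -1.27. SNORD2 differed by -0.74 at day 4. By limma over the 8 detected probes of this class the adjusted p at day 4 were 0.00011 for each U6 probe and 0.00637 for SNORD2. The values are ratios to the miRNAs on the same array, so they show unequal change only.

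For U6, the loess fit within each array is argued against as the whole cause: with median centring the mean of the 2 U6 probes at day 4 was still -1.08 ± 0.28 (SE). SNORD13 at day 4 differed by 0.0909 ± 0.164 (SE, log2), and by -0.01 with median centring. That test against a joint fall of small RNAs other than miRNAs took SNORD13 to be as bright as U6, but its mean log2 intensity was 9.20 against 10.1 and 12.8 for the U6 probes. SNORD2 and SNORD3@, brighter than U6snRNA1, lay lower by 0.74 ± 0.21 and 0.49 ± 0.36 at day 4, so a joint fall is left open. A change in the U6 level of differentiating cells may also remain, with the mean at -1.08 under median centring.

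Probes of other organisms among the 36 calls at day 4 were weighed against binding of a mouse miRNA. Of the 20 tested probes of other organisms that share a number with a called mouse probe, 17 moved the same way, a share of 0.85. This goes with uptake of the mouse miRNA but cannot show it, since only signs were counted. Some lay within their SE of 0, as dre-miR-17a* at -0.05 ± 0.12 and fru-miR-30c at 0.13 ± 0.19 (log2). The opposite-strand probes dre-miR-17a* and dre-miR-133b* were counted as moving the same way. Of the 17, 4 were called, and their calls are part of the pattern weighed. Of the 11 called probes not named for mouse, the others share no number with a called mouse probe, so this leaves aga-miR-7, mghv-miR--14 and the like open.

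Most day 1 calls, 7 of 9, were on probes not named for mouse. Without day 1 replicate 2, the array with the noisier spots, 3 of them were still called: mml-miR-133a, hsa-miR-617 and probe 17881. The count of 3 alone cannot tell whether that array is behind the calls. The sizes argue against that array alone making these differences: all 7 kept their sign and at least 0.758 of their size without it. Of the 4 that lost the call, aga-miR-7 went from -1.19 ± 0.27 to -1.20 ± 0.30 (SE), probe 17950 from 0.62 ± 0.16 to 0.66 ± 0.17, probe 17864 from 0.77 ± 0.17 to 0.65 ± 0.18 and rlcv-miR-rL12 from 0.94 ± 0.21 to 0.71 ± 0.19, with adjusted p between 0.0609 and 0.0927.

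Other splits of the 8 arrays of a comparison, 35 in all with the real one, were counted where they gave as many calls. The planned limit was a share under 0.05, and 1 of 35 is the smallest share possible. Only the real split gave as many probes for day 2 (23, highest other 1), day 4 (36, highest other 2) and day 1 against confluent (9, highest other 0). This argues against chance there but cannot exclude it. For day 1 against proliferating chance is left open. There 2 splits gave as many, the real one with 9 and another with 19. The other split set proliferating replicates 1 and 3 with day 1 replicates 2 and 4 against the rest. That split does not follow the dye orientation. The replicates it set together had the lowest array weights of their groups. These were 0.592 and 0.644 in proliferating cells and 0.238 and 0.599 at day 1, against 0.815 to 1.90 on the rest. What lies behind that split was not tested. Where the real split called 0 probes, all 35 give at least as many by definition, so the splits say nothing on chance at confluence (highest other 2), from day 1 to day 2 (highest other 1) and from day 2 to day 4 (highest other 1). For the time course, only the real grouping among 100 groupings of the 20 arrays gave as many as 43 (highest other 6). The other groupings were drawn at random and did not keep 2 arrays of each dye orientation per group. For the lists, only the real split gave as many at day 1 (2 lists, highest other 1), day 2 (6, highest other 2) and day 4 (7, highest other 2). This argues against chance at days 2 and 4 without excluding it. At day 1 the counts are close. Camera with an estimated correlation gave an adjusted p of 0.387 for both day 1 lists, so chance is left open there. At confluence the real split gave 0 lists, as did all 35, which says nothing on chance.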

How the results depend on the processing

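All alternatives were planned except leaving day 1 replicate 2 out of the shared fit, which was chosen only after the result was seen. No direction of a called named probe or list turned under the alternatives run.

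The count at confluence, 0, became 1 without background correction, with plain subtraction and with the ratio to the pool tested against 0. That ratio, which leaves the spread of the proliferating arrays out, gave 57 at day 1, 52 at day 2, 89 at day 4 and 109 over the time course. Without the dye term the counts were 3, 5 and 19 at days 1, 2 and 4, 4 for day 1 against confluent and 13 over the time course. Median centring gave 12 at day 2, 23 at day 4, 5 for day 1 against confluent and 23 over the time course. Loess fitted on detected spots gave 5 at day 1 and 28 over the time course, and scale normalization gave 5 for day 1 against confluent. With no detection filter 4 probes were called at day 1 and 11 at day 2. With detection on all 20 arrays, which tests fewer probes, 25 were called at day 1 and 2 from day 1 to day 2. Mouse-named probes alone gave 2 at day 1. Fits of only the 2 groups compared gave 5 at day 1 and 11 at day 2. The step from day 1 to day 2 gave 1 with print-tip loess, 2 with median foreground and 4 with array weights. Of the 15 list tests past the threshold, camera with an estimated correlation kept 3 and with a preset correlation 10; median centring, the fit without the dye term and fits of only the 2 groups compared kept 10 each, and loess fitted on detected spots 11. Apart from fewer probes or arrays and the spread left out, the cause was not tested.

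With each array left out the count was 0 at confluence and from day 2 to day 4, and it lay between 4 and 17 at day 1, 9 and 23 at day 2, 30 and 40 at day 4, 35 and 48 over the time course, 5 and 9 for day 1 against confluent and 0 and 2 from day 1 to day 2, where leaving out day 2 replicate 3 gave 2. Without day 1 replicate 2 in the shared fit the counts were 0, 27, 37 and 42 at confluence, day 2, day 4 and over the time course.

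Loess fitted on detected spots moved the median of all tested probes to -0.20 at confluence, -0.35 at day 1, -0.34 at day 2 and -0.18 at day 4, to -0.10 for day 1 against confluent and to 0.15 from day 2 to day 4. The 59 called differences of named probes kept their call in 833 of 946 other values and in 386 of 472 with an array left out. The 946 include Aquantile normalization, which leaves the ratios unchanged and cannot end a call. Of the 59, 57 lay within 1 SD between arrays of the authors' values, but this is no independent support, since the dye orientation was taken from that table. The call of miR-1 at day 2 held in 9 of 25 settings, and that at day 4 ended only with loess on detected spots and with scale normalization. Signal over background limits miR-1, miR-150, miR-155, aga-miR-7, miR-19a and miR-19b, which were near the detection limit on many arrays. Keeping rejected spots, a block for batch and 1 probe per seed family were not run, because the files give no quality flags, batches or sequences. No paired analysis was possible because the labels give no replicate numbers per array.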

Other observations

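miR-500, miR-532, miR-183, miR-298, miR-709 and miR-691 were chosen only after the result was seen, and no further test was run on them.

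Beyond the lists, further mouse miRNAs changed at day 4 against proliferating cells, all on 4 of 4 arrays by limma. miR-500 rose by 0.70 ± 0.14 (SE) and miR-532 by 0.60 ± 0.15 on the log2 scale, with adjusted p of 0.00174 and 0.0164, and both were already higher at day 2, by 0.55 and 0.60; miR-532 was above background on 2 of 4 day 4 arrays and 3 of 4 proliferating arrays. miR-182 and miR-183, whose genes lie in one cluster with Mir96, fell together, by 0.90 ± 0.15 and by 0.70 ± 0.16. miR-298 rose by 0.52 ± 0.15 at day 4. For miR-709 the difference was as large before induction: 0.65 ± 0.16 at confluence (adjusted p = 0.364, not past the threshold), 0.50 ± 0.16 at day 1, 0.60 ± 0.16 at day 2 and 0.59 ± 0.16 at day 4, with calls at days 2 and 4. miR-691 rose by 0.57 ± 0.15 at day 4, and its difference at confluence was already 0.47 ± 0.15 without passing.

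Some neighbours of called miRNAs were too dim for their ratios to be set against those of bright probes. miR-143 rose by 1.18 ± 0.17 at day 4 while its neighbour miR-145, detected on 4 of the 20 arrays, differed by -0.16 ± 0.16. Among probes of the miR-17-92 cluster, miR-17-5p and miR-20a (probe 11008) fell by 1.41 ± 0.19 and 1.45 ± 0.21, against -0.24 ± 0.28 for miR-19a and -0.12 ± 0.19 for miR-19b, which were detected on 9 and 8 arrays. The differences between neighbours were not tested.

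The authors' deposited column for proliferating cells had an R² of 0.0106 on the 20 arrays, against 0.799 to 0.909 for the other columns. What its values hold is not given in the sources used here.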
